A study of Mus musculus with 6 samples.

How the data were processed

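The samples were tumour-associated macrophages (TAM) taken from mouse hepatocellular carcinoma and labelled by the surface receptor TREM2, with 3 TREM2+ and 3 TREM2- libraries. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was used, and libraries were sequenced on an Illumina instrument with paired ends. STAR 2.7.10a, Subread and featureCounts 2.0.3 with the mouse build mm10 are named in the submitters' processing notes. The annotation release, the strand setting and the formula behind the deposited values are not given in the sources used here. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

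The deposited table holds 55291 gene symbols in 6 libraries and is named as TPM. Its values are not TPM per library: the 6 columns together, not each of them, sum to 1000000. The deposited values are therefore treated as a length-scaled signal that the authors did not scale to the depth of each library. The test fixed before the data were examined assumed TPM with no further scaling, and each library was instead rescaled here to a total of 1000000 (called TPM from here on). No column lacked a sample.

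Whole reads were recovered by multiplying the deposited signal by the exon length of each gene in GENCODE M21, an annotation of the same build. Symbols matched for 53292 rows, and of the 36745 matched rows above 0, 98.7% came out whole within 0.01 read in all 6 libraries. Recovered depth ranged from 11522970 to 19975865 reads, which were used to judge precision and in an alternative test. The reads carry no molecular identifiers that could be used here, so read floors cover counting error only. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. Coordinates and gene types are those of GENCODE M21 on mm10.

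Genes with a TPM of at least 1 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Errors after a log2 fold change are standard errors of the limma fit over 3 against 3 libraries, and errors after a TPM are SDs with n = 3. For Trem2 an exact permutation test was added. The 49 gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, where at least 5 members were tested. A list count "adjusted over the list alone" applies the adjustment to the members of that list only. Lists share members, so their results are not independent.

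Genes were named by a rule fixed before the data were examined, as were the lists and the first set of other settings. It takes Trem2, and in each direction the 10 genes with the largest change among those past the threshold with a mean TPM of at least 5 in the higher group and no overlap of the groups, leaving out predicted and unnamed loci. It also takes up to 4 members of each list with the smallest p. The text names only part of the list members so taken, and 1 gene is not reported here. That set covered the pseudocount, the low-value filter, the scaling, a replicate block, the trend, library weights, each library left out, the threshold and the list tests. Added after seeing the data were limma's voom on recovered reads, the deposited values without rescaling, a repeat family left out, both libraries numbered 3 left out, and a minimum mean of 10 recovered reads. The rescaling of each library in the main fit was likewise chosen after the column totals were seen. The repeat family holds 12 genes, namely Gm10800 and those of which at least 10% of the stretches of 20 bases occur in it.

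The fit was tested on simulated reads for 52818 genes, with 200 changed genes in each of 20 simulations. With the fitted spread of each gene, 6.5% of the genes raised 2-fold, 64.4% of those raised 4-fold and 92.6% of those raised 8-fold were recovered, as were 2.5% of those lowered 2-fold and 56.9% of those lowered 4-fold. False calls made up 20.9% of all calls and 6.84% of calls on features with a mean of at least 10 reads, so the adjusted threshold of 5% was exceeded in both, and most for features with few reads. With the repeat family set to the median spread, false calls were 14.5% and 3.37%, and 66.75% of the genes raised 4-fold and 72.25% of those lowered 4-fold were recovered. The first simulation tried used the raw residual spread of each gene, which holds sampling noise that the drawn reads add again. The fitted spread of the other simulations holds it too, so this does not set them apart. The raw spread gave 40.9% and 31.4% false calls and recovered 34.2% of the genes raised and 27.4% of those lowered 4-fold. The other simulations were chosen after that result. A planted list of genes, all raised 2-fold, was called in every simulation. Noise was drawn for each gene separately, so the simulated lists held no correlation between genes. The simulations therefore do not show how camera behaves on correlated lists.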

Results

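Messenger RNA was sequenced from macrophages of mouse liver tumours labelled TREM2+, for a lipid-sensing receptor of the immunoglobulin superfamily, and from macrophages of such tumours labelled TREM2-. There were 3 TREM2+ and 3 TREM2- libraries. Recovered reads came to 17229420, 15606882 and 12588180 in TREM2+ replicates 1, 2 and 3, and to 19975865, 15399883 and 11522970 in TREM2- replicates 1, 2 and 3. No pair of replicates agreed within sampling noise, with chi-square values per degree of freedom between 77.7 and 238. The libraries differed in composition within both groups. Transcripts of the Gm10800 repeat family took 0.70%, 5.05% and 17.5% of the TPM in the TREM2+ libraries and 0.43%, 12.9% and 24.6% in the TREM2- libraries. Mitochondrially encoded transcripts took 10.02%, 3.78% and 6.72% against 12.3%, 2.42% and 2.96%. On the first principal component, which held 34.8% of the variance, the groups did not overlap: the TREM2+ libraries lay at -30.0, -13.6 and -42.4 and the TREM2- libraries at 58.0, 8.37 and 19.7, with TREM2- replicate 1 farthest from the rest.

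**Figure D1:**
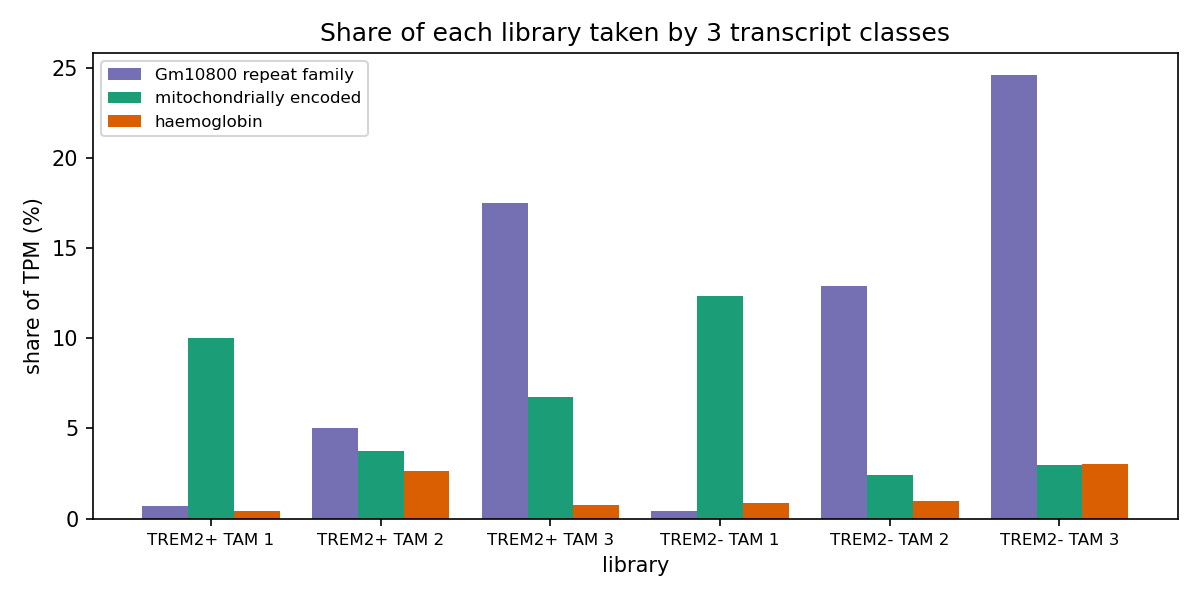
Share of the TPM of each library, in percent, taken by the Gm10800 repeat family, by mitochondrially encoded transcripts and by haemoglobin transcripts; each bar is 1 library. The repeat family ranged from 0.43% in TREM2- replicate 1 to 24.6% in TREM2- replicate 3.

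Trem2 itself (ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147, mm10) checks the labels and is not a finding. It stood at 37.0 ± 5.51 TPM (SD, n = 3) in the TREM2+ libraries and 19.5 ± 2.28 TPM in the TREM2- libraries, with no overlap of the groups. The log2 fold change was 0.89 ± 0.22, which is 1.85-fold, with an adjusted p of 0.0855 in limma, so it did not pass the threshold. The exact permutation test gave p = 0.1, two-sided, which is the smallest that 3 against 3 libraries allow. A larger log2 fold change was found for 706 genes, or 5.12% of those tested. Trem2 was higher in all 3 TREM2+ libraries, and its transcripts were also present in every TREM2- library, with 745, 755 and 673 reads in replicates 1, 2 and 3.

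The comparison asks how the transcriptomes of TREM2+ and TREM2- macrophages of the tumour differ. The TREM2+ libraries carried more transcripts of complement C1q, scavenger receptors and Kupffer cell genes, and of the arginine-degrading enzyme Arg1. They also carried more of genes of lipid-associated macrophages such as Spp1 and Mmp12. Of the lists fixed for such genes, 16 of 20 complement and scavenger-receptor genes, 12 of 19 Kupffer cell genes and 12 of 25 lipid-associated macrophage genes passed. With an estimated correlation none of the 3 lists did (adjusted p = 0.0509, adjusted p = 0.116 and adjusted p = 0.0803). Fry called all 3 lists higher (adjusted p = 0.0032, adjusted p = 0.0071 and adjusted p = 0.0071). C1qc reached 2512 ± 290 TPM against 411 ± 141 TPM (SD, n = 3), and Arg1 reached 3507 ± 1210 TPM against 385 ± 55.5 TPM. Of 17 genes usually read as endothelial 13 were also higher, among them Clec4g at 159 ± 32.8 against 13.2 ± 5.88 TPM. That list had adjusted p = 0.118 with an estimated correlation and adjusted p = 0.0071 in fry. A library holds RNA of many cells, so none of these transcripts is assigned to a cell type here. Lower in the TREM2+ libraries were the monocyte surface gene Ly6c2, the basophil protease Prss34, and several immunoglobulin variable segments. Prss34 and, of the segments, only Ighv1-15 stayed called in all 6 fits that leave out 1 library. Ly6c2, uncertain because of near-identical copies, stayed called in 4.

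Of 13788 genes tested with limma, 282 were higher and 51 were lower in the TREM2+ libraries at an adjusted p under 0.05. Of the calls, 84.7% were higher. That share was 69.1% on the deposited values without rescaling, 72.2% with voom on recovered reads, 71.5% with library weights and 73.8% without the repeat family. At an unadjusted p under 0.05, 1027 genes were higher and 736 lower, and this balance turned round in 5 settings. Higher and lower genes then numbered 1079 and 1755 with voom, 1114 and 2113 without the repeat family, 645 and 674 on the deposited values, 767 and 792 without TREM2+ replicate 2, and 808 and 882 without TREM2- replicate 3. In 16.7% of genes the groups did not overlap, where chance gives 10%. The count of higher genes fell to 148 without TREM2+ replicate 1, 153 without TREM2+ replicate 3 and 116 without TREM2- replicate 3. That of lower genes moved to 7 without TREM2- replicate 1, 10 without TREM2- replicate 3 and 105 without TREM2- replicate 2. Without both libraries numbered 3 limma called 0 genes, with 636 higher and 444 lower at an unadjusted p under 0.05. Of the lower calls, 21 rested on a mean under 10 recovered reads per library, as did 5 of the higher calls, and simulated libraries gave an excess of false calls on such features.

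The largest increases by the naming rule were those of Cyp4b1, a cytochrome P450 (chromosome 4, 115624725 to 115647723), with a log2 fold change of 3.60 ± 0.46, and of Clec4g, a lectin of liver sinusoidal endothelium (chromosome 8, 3707064 to 3720651), with 3.57 ± 0.33. They were followed by Igfbp7 (3.26 ± 0.26), Gpihbp1, the capillary anchor of lipoprotein lipase (3.23 ± 0.39), the water channel Aqp1 (3.16 ± 0.28), Gpr182 (3.13 ± 0.23), Arg1 (chromosome 10, 24915221 to 24927484, 3.13 ± 0.30), Clec4f (3.11 ± 0.37), Cd5l (3.08 ± 0.35) and Lyve1 (2.92 ± 0.36). Adjusted p-values of these 10 genes in limma lay between 0.0022 and 0.0061, and each stayed called in all 6 fits that leave out 1 library.

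**Figure D2:**
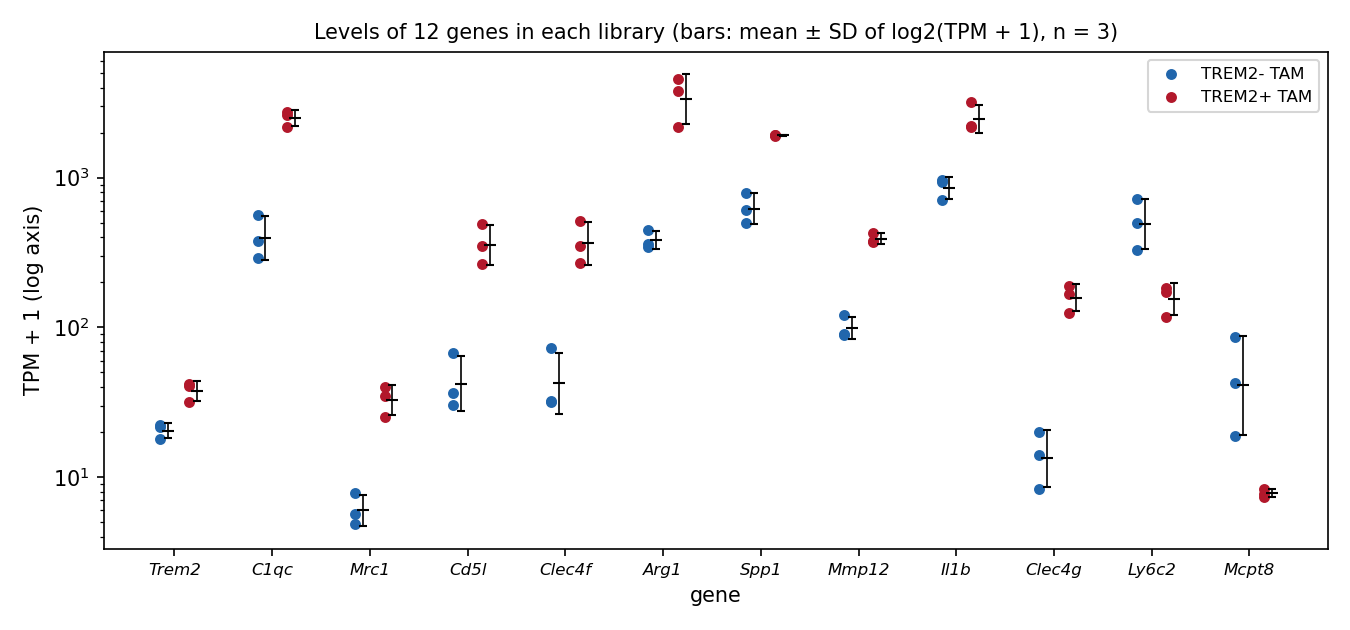
TPM + 1 of 12 genes on a log axis; each point is 1 library, red for TREM2+ and blue for TREM2- macrophages, and bars give the mean ± SD of log2(TPM + 1) with n = 3. C1qc, Cd5l, Clec4f, Arg1 and Clec4g lie higher in all 3 TREM2+ libraries, and Ly6c2 and Mcpt8 lie lower.

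Among complement and scavenger-receptor macrophage genes, 16 of 20 tested members rose, 0 fell and 4 did not pass, and 20 passed when adjusted over the list alone. C1qb, a subunit of the complement initiator C1q, rose from 989 ± 373 to 6170.2 ± 832 TPM, a log2 fold change of 2.7 ± 0.30. The mannose receptor Mrc1 rose by 2.45 ± 0.27 and the folate receptor Folr2 by 2.37 ± 0.26 on the log2 scale. The list's median was 1.78, with an adjusted p of 1.72e-34 in camera and adjusted p = 0.0509 with an estimated correlation. Of the 16 genes, 11 stayed called in all 6 fits that leave out 1 library.

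Kupffer cell genes, which mark the resident macrophages of the liver, rose in 12 of 19 tested members and fell in 0, with 7 not passing and 17 passing when adjusted over the list alone. Among the 12, Cdh5 (1.55 ± 0.26) is also in the list of endothelial cell genes. The 7 that did not pass had log2 fold changes from 0.11 (Adgre1) to 1.59 (Fabp7). Clec4f rose from 44.6 ± 23.4 to 376 ± 125 TPM and the complement receptor Vsig4 from 47.3 ± 8.83 to 332 ± 114 TPM. The iron exporter Slc40a1 had a log2 fold change of 2.27 ± 0.25 and the complement component C6 of 2.38 ± 0.21. The median was 1.88, with adjusted p = 0.116 with an estimated correlation, and 7 of the 12 genes stayed called in all 6 fits.

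Of 25 lipid-associated macrophage genes, 12 rose, 0 fell and 13 did not pass. Adjusted over the list alone, 20 were higher and 1 was lower. The 13 that did not pass had log2 fold changes from -1.08 (Anxa1) to 1.08 (Syngr1). Among them were Gpnmb (1.08), Cd9 (0.81) and Lgals3 (0.31), named here after their values were seen. Spp1, which encodes osteopontin, rose from 632 ± 150 to 1913 ± 17.7 TPM, and the macrophage elastase Mmp12 from 98.9 ± 18 to 391 ± 32.7 TPM. The fatty acid transporter Cd36 had a log2 fold change of 2.03 ± 0.31 and the proton pump subunit Atp6v0d2 of 1.80 ± 0.23. The list's median was 1.08, with adjusted p = 0.0803 with an estimated correlation. Only Atp6v0d2 and Mmp12 of the 12 stayed called in all 6 fits that leave out 1 library.

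Lysosome genes rose in 5 of 34 members, 7 adjusted over the list alone, among them the proteases Ctsb (1.33 ± 0.21) and Ctsd (1.29 ± 0.23) and the galactosidase Gla (1.20 ± 0.24), and adjusted p = 0.387 with an estimated correlation. In the list of fatty acid uptake and storage genes 5 of 19 rose, 7 adjusted over the list alone, including the fatty acid binding genes Fabp4 (2.05 ± 0.35) and Fabp5 (2.03 ± 0.41) and the lipid droplet gene Hilpda (1.51 ± 0.28), and adjusted p = 0.387 with an estimated correlation. LXR target and cholesterol efflux genes rose in 4 of 17 members, and adjusted over the list alone 6 were higher and 1 lower. The cholesterol exporter Abca1 rose by 1.73 ± 0.28 and the apolipoprotein Apoe from 4621 ± 1908 to 16239 ± 4435 TPM, and adjusted p = 0.423 with an estimated correlation. None of the 5 fatty acid uptake and storage genes, 1 of the 5 lysosome genes (Atp6v0d2) and 1 of the 4 LXR target genes (Abca1) stayed called in all 6 fits that leave out 1 library; Hilpda stayed called in 2 fits, and Apoe and Gla in 1 each. Camera called none of cholesterol biosynthesis genes (21 members, median -0.17), fatty acid oxidation genes (23 members, median -0.08) and oxidative phosphorylation genes (45 members, median -0.13), and 0 of their members passed, also when adjusted over the list alone.

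Chemokines that attract monocytes and neutrophils rose in 6 of 12 tested genes, 10 adjusted over the list alone, with a median of 2.12 and adjusted p = 0.116 with an estimated correlation. Ccl8 rose from 201 ± 52.9 to 1261 ± 412 TPM, and Cxcl2, a neutrophil attractant, from 365 ± 194 to 1579.96 ± 514 TPM. Inflammatory cytokine and NF-kB target genes rose in 7 of 23 members, 13 adjusted over the list alone, with adjusted p = 0.164 with an estimated correlation. The cytokine Il1b rose from 865 ± 139 to 2520.2 ± 572 TPM and Il1a had a log2 fold change of 1.58 ± 0.27; none of the 7 genes stayed called in all 6 fits that leave out 1 library. T cell attracting chemokine genes rose in 2 of 9 members, Cxcl16 (1.71 ± 0.25) and Cxcl9 (1.82 ± 0.31), 4 adjusted over the list alone, with adjusted p = 0.385 with an estimated correlation. Of the monocyte and neutrophil attracting chemokines 2 of the 6, among them Ccl8, stayed called in all 6 fits, and Cxcl2 in 3, while of the T cell attracting chemokines Cxcl16 did and Cxcl9 stayed called in 4.

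Interferon-gamma response genes rose in 2 of 24 members, Cxcl9 and the checkpoint ligand Cd274 (1.70 ± 0.34, called in 2 of the 6 fits that leave out 1 library), 3 adjusted over the list alone, with adjusted p = 0.628 with an estimated correlation, and the camera call was lost without both libraries numbered 3 (median -0.05). None of 25 type I interferon response genes passed, 2 did adjusted over the list alone, and Rsad2 had a log2 fold change of 1.30 ± 0.31. The camera call of the type I interferon response genes (median 0.14, adjusted p = 0.809 with an estimated correlation) was lost without TREM2+ replicate 1 (median 0.05), TREM2+ replicate 3 (0.17) or TREM2- replicate 3, where the median was -0.08, and without both libraries numbered 3 (-0.09). Of 15 MHC class II presentation and costimulation genes none passed, while adjusted over the list alone 8 were higher and 1 lower. The antigen presentation gene H2-Aa stood at 2524 ± 622 against 999 ± 316 TPM (adjusted p = 0.0663 in limma), and the list had adjusted p = 0.419 with an estimated correlation.

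Alternative activation and immune checkpoint genes rose in 6 of 24 members, 8 adjusted over the list alone, with adjusted p = 0.385 with an estimated correlation. They were led by Arg1, Mrc1 and the eosinophil attractant Ccl24 (1.90 ± 0.23), and the ectonucleotidase Nt5e rose by 1.23 ± 0.23. Those 3 stayed called in all 6 fits that leave out 1 library and Nt5e in 1. Arginine, tryptophan and amino acid metabolism genes rose in 3 of 17 members, Arg1, the arginine transporter Slc7a2 (1.64 ± 0.22) and the nitric oxide synthase Nos2 (2.43 ± 0.47), of which Arg1 and Slc7a2 stayed called in all 6 fits and Nos2 in 3. Adjusted over the list alone 5 were higher and 2 lower, with adjusted p = 0.606 with an estimated correlation; the camera call was lost in 8 of 21 settings. These were median-of-ratios scaling, quantile normalization, library weights, voom (median -0.13), at least 10 reads, and the fits without TREM2- replicate 1, TREM2- replicate 3 or both libraries numbered 3.

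Hypoxia response genes rose in 3 of 19 members, 12 adjusted over the list alone, among them the glucose transporter Slc2a1 (1.22 ± 0.22) and the vasodilator peptide gene Adm (1.44 ± 0.30), with adjusted p = 0.184 with an estimated correlation. Glycolysis genes rose in 2 of 21 members, Slc2a1 and Pfkfb3 (1.12 ± 0.23), 14 adjusted over the list alone, with adjusted p = 0.29 with an estimated correlation. None of the 3 hypoxia response genes and none of the 2 glycolysis genes stayed called in all 6 fits that leave out 1 library: Slc2a1 and Adm did in 1 fit each, the one without TREM2- replicate 2, and Pfkfb3 in 0. Extracellular matrix remodelling and angiogenesis genes rose in 6 of 24 members, 9 adjusted over the list alone, with adjusted p = 0.0509 with an estimated correlation. They included the proteases Mmp13 (2.13 ± 0.33) and Mmp14 (1.62 ± 0.23) and the growth factor Igf1 (2.08 ± 0.29). Efferocytosis and phagocytosis genes rose in 8 of 22 members, 12 adjusted over the list alone, with adjusted p = 0.209 with an estimated correlation. The receptor Axl (1.72 ± 0.25) and its ligand Gas6 (2.35 ± 0.27) were among them. NRF2 antioxidant and iron handling genes rose in 5 of 21 members, 9 adjusted over the list alone, with adjusted p = 0.29 with an estimated correlation, and the haem oxygenase Hmox1 rose from 165 ± 12.5 to 764 ± 319 TPM. In all 6 fits 4 of the 6 matrix and angiogenesis genes, 4 of the 8 efferocytosis genes and 3 of the 5 NRF2 and iron genes stayed called, among them Mmp13, Mmp14, Igf1, Axl and Gas6 but not Hmox1, which did in 5.

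Macrophage transcription factor genes rose in 3 of 25 members, also 3 adjusted over the list alone, among them the oxysterol receptor Nr1h3 (1.91 ± 0.32) and Maf (1.45 ± 0.25), with adjusted p = 0.628 with an estimated correlation. None of 20 TREM2 and TYROBP signalling genes passed, also when adjusted over the list alone, and their median was -0.10. Immediate early and dissociation stress genes rose in 1 of 24 members, Ier3 (1.88 ± 0.32), also 1 adjusted over the list alone, with adjusted p = 0.809 with an estimated correlation. None of the 3 transcription factor genes stayed called in all 6 fits that leave out 1 library, with Nr1h3 in 4 and Maf in 3, and Ier3 stayed called in 3. Neither of the lists of unfolded protein and integrated stress response genes (21 members, median 0.20) and cell cycle genes (31 members, median -0.28) held a gene that passed, with 1 and 0 passing when adjusted over the list alone, and both had adjusted p = 0.809 with an estimated correlation. The camera calls of these 3 lists were lost in some settings. For immediate early genes they ended with quantile normalization, with library weights (median -0.09), and without TREM2+ replicate 2 or TREM2- replicate 1. For unfolded protein genes they ended with a TPM of at least 5, at least 10 reads, quantile normalization, library weights or the deposited values, and without TREM2+ replicate 1, TREM2- replicate 1, TREM2- replicate 3 or both libraries numbered 3. For cell cycle genes they ended on the deposited values, and without TREM2+ replicate 1, TREM2+ replicate 3 or both libraries numbered 3.

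**Figure D3:**
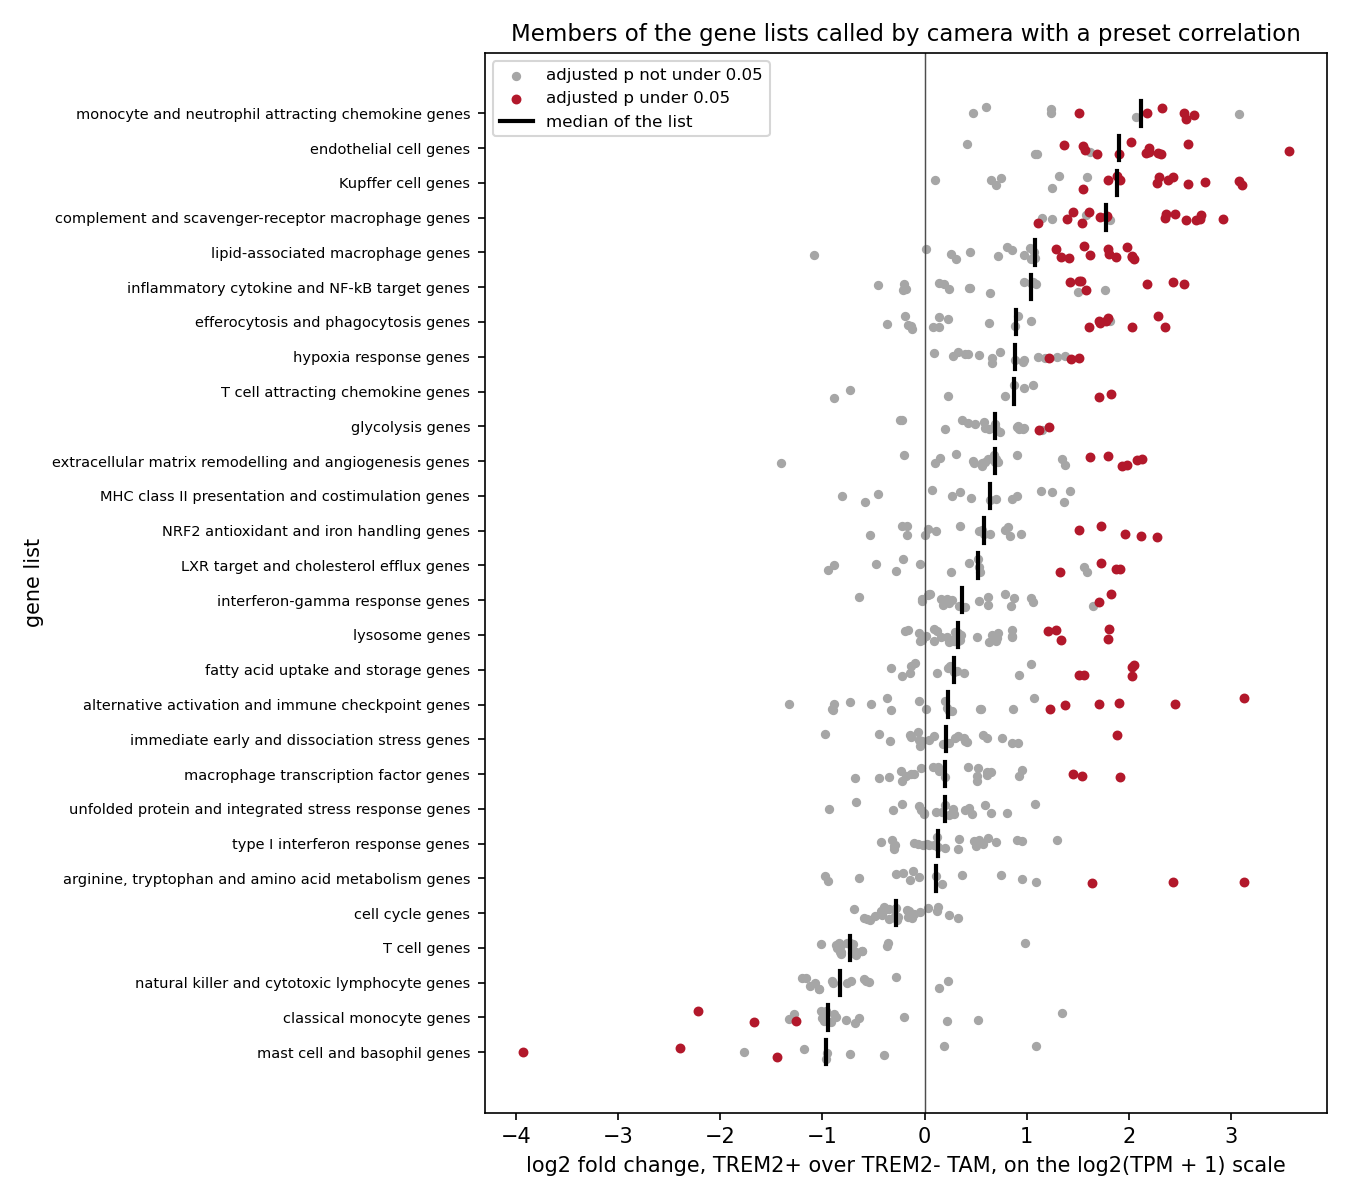
Log2 fold change of the tested members of the 28 gene lists called by camera with the preset correlation, TREM2+ over TREM2- macrophages, on the log2(TPM + 1) scale; each point is 1 gene, red where its adjusted p is under 0.05, and black bars are list medians. Medians run from 2.12 for chemokines that attract monocytes and neutrophils to -0.96 for mast cell and basophil genes.

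Classical monocyte genes fell in 3 of 20 members and rose in 0, with 11 lower when adjusted over the list alone, a median of -0.94 and adjusted p = 0.419 with an estimated correlation. Ly6c2 stood at 156 ± 35.6 against 515 ± 194 TPM, Ly6a2 at 111 ± 37.7 against 515 ± 154 TPM and Ifitm6 at 324 ± 84.8 against 768 ± 141 TPM. Ly6c2 and Ly6a2 belong to a family of near-identical copies between which reads may have been split, so both are uncertain. None of the 3 stayed called in all 6 fits that leave out 1 library.

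Mast cell and basophil genes fell in 3 of 11 members, with 4 lower and 1 higher when adjusted over the list alone, and adjusted p = 0.434 with an estimated correlation. Prss34 (chromosome 17, 25298394 to 25300165) stood at 4.85 ± 4.72 against 69.8 ± 8.77 TPM, a log2 fold change of -3.93 ± 0.52, and stayed called in all 6 fits that leave out 1 library. Mcpt8 had -2.39 ± 0.47 and the carboxypeptidase Cpa3 -1.44 ± 0.29, and each stayed called in only 2 of the 6 fits. Mcpt8 stood at 85.1, 17.9 and 41.4 TPM in TREM2- replicates 1, 2 and 3 against 6.82 ± 0.49 TPM, and of these fits kept its call in those without TREM2+ replicate 1 and without TREM2- replicate 2. Cpa3 kept its call in those without TREM2- replicate 1 and without TREM2- replicate 2. None of 20 T cell genes (median -0.73, adjusted p = 0.68 with an estimated correlation) and none of 16 natural killer and cytotoxic lymphocyte genes (median -0.83, adjusted p = 0.628 with an estimated correlation) passed, also when adjusted over the list alone. Lck stood at 39.3 ± 1.5 against 91.6 ± 60.5 TPM and Gzma at 183 ± 67.8 against 403 ± 117 TPM. These lists were highest in TREM2- replicate 1, where the mean log2(TPM + 1) of T cell genes was 5.80 against 4.36 and 4.52 in the other TREM2- libraries and 4.14 to 4.35 in the TREM2+ libraries. Without that library the medians were -0.30 for T cell genes, -0.19 for natural killer and cytotoxic lymphocyte genes and -0.71 for mast cell and basophil genes. With library weights the camera call of natural killer and cytotoxic lymphocyte genes ended, with a median of -0.11 and an adjusted p of 0.14.

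Further large decreases by the naming rule were those of Ighv1-15 (-3.92 ± 0.28), Igkv13-84 (-3.27 ± 0.62), Igkv12-41 (-3.09 ± 0.57) and Ighv1-52 (-2.44 ± 0.42), immunoglobulin variable segments whose reads can be shared with similar segments, and of the glycosyltransferase gene Galnt9 (-2.02 ± 0.34). Of these, Ighv1-15 stayed called in all 6 fits that leave out 1 library, each of the other 3 segments in 4 and Galnt9 in 3; without TREM2- replicate 3 only Ighv1-15 did. Traj21, a T cell receptor joining segment, had 0 reads in the 3 TREM2+ libraries and 16, 1 and 3 reads in TREM2- replicates 1, 2 and 3. Mir3473d, a microRNA gene, had 0 reads against 4, 2 and 5. Both rest on few reads, too few for a fold that holds in each library. Traj21 stayed called in 1 and Mir3473d in 3 of the 6 fits that leave out 1 library.

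Endothelial cell genes rose in 13 of 17 members and fell in 0, with 16 higher when adjusted over the list alone, a median of 1.91 and adjusted p = 0.118 with an estimated correlation. The endoglin gene Eng stood at 10.2 ± 1.67 against 1.46 ± 0.46 TPM, Egfl7 at 17.7 ± 4.77 against 2.19 ± 0.98 TPM and the scavenger receptor Stab2 at 9.48 ± 3.23 against 1.10 ± 0.32 TPM. The members that did not pass, Pecam1, Oit3, Emcn and Flt1, are named here after their values were seen. Pecam1 stood at 13.2 ± 1.97 against 6.25 ± 3.48 TPM and Oit3 at 26.4 ± 3.50 against 8.76 ± 5.35 TPM. Emcn stood at 2.20 ± 0.28 against 0.50 ± 0.25 TPM and Flt1 at 3.13 ± 1.47 against 2.04 ± 0.80 TPM. Flt1 had the smallest log2 fold change of the list, 0.42. Of the 13 genes, 6 stayed called in all 6 fits that leave out 1 library.

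Other lists of cell types and RNA quality were not called by camera. In 3 of them 1 member rose, namely Cadm1 (1.69 ± 0.20) of the 14 conventional dendritic cell 1 genes, Pf4 (2.56 ± 0.29) of the 10 platelet and megakaryocyte genes and Fabp4 of the 18 non-classical monocyte genes. In 2 of them 1 member fell, the chemokine receptor Ccr7 (-1.19 ± 0.24) of the 13 migratory mature dendritic cell genes and the antimicrobial peptide gene Camp (-1.78 ± 0.34) of the 20 neutrophil genes. Cadm1 and Pf4 stayed called in all 6 fits that leave out 1 library, Fabp4 in 5, Camp in 2 and Ccr7 in 1. Adjusted over the list alone, 4 neutrophil genes were higher and 6 lower, 2 migratory dendritic cell genes were higher and 3 lower, 2 platelet genes were higher, and the counts of the other lists in this group did not change. Medians of these lists were -0.35 for conventional dendritic cell 1, -0.11 for platelet, -0.30 for non-classical monocyte, -0.35 for migratory dendritic cell and 0.21 for neutrophil genes. Signs differed for neutrophil genes, with a mean of -0.20, and for platelet genes, with a mean of 0.19. No member passed among conventional dendritic cell 2 (median -0.68), erythroid (-0.57), plasma cell (-0.58), stellate cell and fibroblast (0.14), hepatocyte (0.20), plasmacytoid dendritic cell (-0.20), liver tumour and oncofetal (-0.32) and B cell genes (-0.11). Nor did any pass among mitochondrially encoded transcripts (0.43) and cytosolic ribosomal protein genes (-0.02). For ribosomal protein and B cell genes camera's direction was higher although the medians were negative. Nuclear retained transcripts, with 3 tested members, and cholangiocyte genes, with 4, were too few to test as lists.

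Camera with the preset correlation called 23 of 47 lists higher and 5 lower, and with an estimated correlation it called 0 in either direction. Fry, which asks whether the genes of a list move on balance one way, called 11 lists higher and 0 lower. These were the complement and scavenger-receptor, Kupffer cell, lipid-associated macrophage, endothelial cell, matrix and angiogenesis, and monocyte and neutrophil attracting chemokine lists. The hypoxia, glycolysis, inflammatory cytokine, efferocytosis and NRF2 lists were the others, with adjusted p-values in fry from 0.0032 to 0.0388 over all 11. Another split of the same 6 libraries gave camera 31 called lists with the preset correlation, though such a split keeps part of the group difference.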

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

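Chosen after seeing the data were voom on recovered reads, the deposited values without rescaling, the repeat family left out, both libraries numbered 3 left out, and the minimum of 10 recovered reads. So was the rescaling of each library in the main fit, and without it 206 genes were higher and 92 lower. No result named in the text reversed its direction with a call under any alternative. Of the 72 called genes named in the text, 30 stayed called in all 20 other settings that keep at least 5 libraries, 64 did with voom, 33 with no low-value filter and 0 without both libraries numbered 3. Of the 28 lists called by camera, 21 kept the call in all 21 settings that use its preset correlation. The higher genes (282) numbered 95 with no filter, 976 with library weights, 444 with voom, 459 with at least 10 reads, 101 at an adjusted p under 0.01 and 0 without both libraries numbered 3, where fewer libraries were fitted. The lower genes (51) numbered 31 with a pseudocount of 0.1, 3 with no filter, 98 with median-of-ratios scaling, 121 with quantile normalization, 389 with library weights, 171 with voom, 92 on the deposited values, 101 without the repeat family, 4 at an adjusted p under 0.01 and 0 without both libraries numbered 3. Leaving out 1 library gave 116 to 342 higher and 7 to 105 lower genes. Lists numbered 20 to 24 higher and 4 to 11 lower without 1 library, 0 and 0 with an estimated correlation, and 11 and 0 with fry. Trem2 passed the threshold with library weights (0.90, adjusted p = 0.0065 in limma) and with voom (0.87, adjusted p = 0.0353), against adjusted p-values from 0.0582 to 0.56 in the others. The cause of these moves was not tested unless stated. The replicate block gave 116 higher and 10 lower genes. Deviations of same-numbered libraries had correlations of 0.19, -0.03 and 0.22, against -0.38 to 0.13 for libraries of different numbers. Recovered reads fell and the repeat family share rose from replicate 1 to 3 in both groups. A pair or batch shared by number is therefore possible, but the labels state none and the main fit holds none. Few reads limit the short features: 21 of the lower calls had a mean under 10 reads.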

Other observations

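The tests on other splits for genes and for camera, on the repeat family, on the library TREM2- replicate 1, on receptor segments, on endothelial genes without the added 1, and on other cell types against endothelial genes were chosen after the results were seen.

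Immunoglobulin variable segments formed a group that no list held. Of 148 tested segments 7 fell and 0 rose, 110 had a negative log2 fold change, and their median was -0.77. Their camera p was 1.33e-05 with the preset correlation, but p = 0.334 with an estimated correlation and 0.265 in fry. T cell receptor segments had 95 tested members, of which 3 fell and 0 rose, 83 were negative, and the median was -0.61, with p = 2.97e-06, p = 0.164 with an estimated correlation and 0.111 in fry. TREM2- replicate 1 stood apart: the mean log2(TPM + 1) of immunoglobulin segments was 4.77 there, against 2.66 and 4.03 in TREM2- replicates 2 and 3 and 2.80, 3.56 and 2.95 in TREM2+ replicates 1, 2 and 3. Without that library the median was -0.29 over 127 immunoglobulin segments, of which 3 fell and 1 rose, and -0.23 over 78 T cell receptor segments, of which 0 fell and 2 rose. Camera with the preset correlation then gave p = 0.000499 and p = 0.00381, lower for both, and an estimated correlation was not tried there. Segments are short and similar to one another, so single members are uncertain.

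The 6 libraries make 10 splits into 3 against 3, too few for a share under 0.05. The real split called 333 genes and the highest other split 3, so that 1 of the 10 splits, the real one itself, called that many. For camera the real split called 28 lists and the highest other 31, and 3 splits called at least 28, the real one included, so camera with the preset correlation also calls many lists between libraries of mixed groups. For fry the real split called 11 lists and the highest other 0, so that 1 split, again the real one, called that many. Every other split sets unequal mixes of both groups against each other. It keeps part of the real difference and adds the rest to its spread. The counts of the other splits are therefore not those of libraries without a group difference.

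Endothelial cell genes had a median log2 fold change of 1.91, with 13 of 17 members higher in the TREM2+ libraries and 4 not passing. The list had adjusted p = 0.118 with an estimated correlation and adjusted p = 0.0071 in fry. Of the members, 2 are also in other lists, Cdh5 among Kupffer cell genes and Stab2 among efferocytosis and phagocytosis genes. The share of the repeat family in the library totals is argued against by its size. The family took at most 24.6% of a library, and with it left out the median was 1.87. These shares allow only a small shift, so the outcome of leaving the family out was fixed in advance. Endothelial cells or their RNA as one source stay open, beside a difference of the macrophages themselves, which was not tested. Of the 10 largest increases by the naming rule, Clec4g is in the endothelial list and Clec4f and Cd5l are in the Kupffer cell list. The capillary gene Gpihbp1, Igfbp7, Aqp1, Gpr182 and Cyp4b1 are in no list, and their cell of origin was not tested. The endothelial list may therefore not hold all endothelial genes among the increases. One source would give its genes a common fold. Of the members, 0 had a 95% interval wholly below 0.95, the midpoint between no change and the median. But Clec4g lay wholly above the median, and 3 members, Emcn, Flt1 and Pecam1, lay wholly below it. Without the added 1, which compresses low members, the median log2 ratio was 3.10, with 0 members wholly above it and 3 below, again with Flt1 and Pecam1. The members thus neither share 1 fold nor exclude a common source beside a level of their own in macrophages.

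More genes were called higher than lower, 84.7% of the calls, and the library TREM2- replicate 1 is argued against as the source of this balance, since 97.1% of the calls were higher without it, with 1398 higher and 421 lower genes at an unadjusted p under 0.05. The share of the repeat family in the library totals stays open. With the family left out 73.8% of the calls were higher, with 284 higher and 101 lower, but at an unadjusted p under 0.05 the balance turned to 1114 higher and 2113 lower genes. The balance also turned with voom, so it is not read as a difference between the groups, and no biological explanation was tested.

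Basophil, T cell and natural killer genes were lower in the TREM2+ libraries as lists in camera with the preset correlation, with single calls only for basophil genes. The calls were lost with an estimated correlation (adjusted p = 0.434, adjusted p = 0.68 and adjusted p = 0.628), fry called 0 lists lower, and the natural killer call ended with library weights. A lower share of macrophages in the TREM2- libraries could raise the genes of other cell types there, but endothelial genes moved the other way. Within libraries, the group difference of the list mean less the endothelial mean was -2.99 ± 0.31 (SE) for basophil genes. It was -2.50 ± 0.32 for T cell and -2.58 ± 0.38 for natural killer genes, and the groups did not overlap in any of them. This decides nothing, since the endothelial list was known to be higher when the comparison was chosen. A lower share also need not raise every other cell type alike. The planned comparison of basophil with neutrophil genes (-0.93 ± 0.58, under 2 standard errors though the groups did not overlap) decides nothing either, since neutrophil members went both ways. Such a lower share and a difference in the cells caught in the 2 groups stay open. The library TREM2- replicate 1, where the 3 lists were highest, stays open too.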
